A study of Mus musculus with 4 samples.

How the data were processed

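Total RNA from mouse embryonic stem cells at day 0 and from epiblast-like tissue at day 3 of an aggregation culture named SFEBq was labelled with biotin and hybridized to Affymetrix expression arrays. Each day was represented by 2 samples, numbered 1 and 2 in the labels, so that 4 arrays were compared. The replicates were not stated to be separate cultures, so p-values measured only the spread between these samples, which may be technical. The number of arrays limited the precision.

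The deposited table held log2 values, 1 per probe set and array. The submitters' processing notes named RMA, a method that corrects background, makes the arrays' distributions alike and summarises the probes of a probe set, and R 2.13.0. Further settings were not given in the sources used here. The unit was checked on the values, whose quartiles were close between arrays (first quartile 4.30 to 4.33, median 5.78 to 5.79, upper quartile 8.07 to 8.08). RMA forces distributions to be alike, so a change in the total amount of RNA per cell could not be seen, and it compresses differences of dim probe sets. No detection calls were used, so a level near or below the first quartile was not separated from background.

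The table had 45101 probe sets, of which 64 were controls. Through the platform annotation, 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none, the controls among the last. No gene was named from a probe set with several symbols. Gene identifiers of 34754 probe sets were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols had to be updated. The sources used here named no genome build, so the table served for names and for chromosomes only. Each of the 18193 genes was represented by its probe set with the highest mean over all 4 arrays, a choice that did not use the day labels. Such a mean can favour a probe set that is very high on 1 day, so the choice is not independent of the size of a difference. For 9010 genes more than 1 probe set was present. Members of multigene families can share probes, and values of such genes (Pramel6, Usp17la, Tcstv1) are less certain.

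Differences between days were fitted in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend), with no covariate. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 18193 genes, and a gene was called at an adjusted p under 0.05. Log2 differences are day 3 minus day 0 and are given with the standard error of the fit. The model had 2 residual degrees of freedom per gene, and the shared variance estimate added about 8.02. A total of 22 gene lists, with 372 entries, were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Of the entries, 342 were measured, and the other 30 were not analysed here, 1 of them being an older symbol of a gene already in its list. Some genes stood in more than 1 list. Camera with an estimated correlation, camera on ranks and fry, which asks whether a list's genes move one way on balance, were alternatives. With an estimated correlation camera rested on 2 residual degrees of freedom, so it had little power to call a list.

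The groups, tests, lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took the 12 largest rises and the 12 largest falls among called genes whose arrays did not overlap between days, the 3 members of each list with the largest difference, and 11 genes set in advance (Pou5f1, Sox2, Nanog, Zfp42, Klf4, Fgf5, Otx2, Dnmt3b, Sox1, T and Gata6). It gave 85 genes, and T was not analysed here. A further 25 genes were chosen after their values were seen. They are 24 list members, mostly from small counts, whose calls held in the alternatives computed for single genes that kept the gene, except the unmoderated test, and Xist. Genes of families described among the other observations were also chosen after their values were seen.

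The alternatives were a fit without the intensity trend, a robust variance fit, an unmoderated test per gene, quantile normalization of the arrays again, median centring, genes above the median level only, the mean of a gene's probe sets, leaving out probe sets marked as matching several transcripts, the replicate number as a block, each array left out in turn, every probe set tested, an adjusted p under 0.01, and limma's treat against a log2 difference of 1. The last 3 were computed for counts of genes or probe sets, not for single genes. The procedure was tested on simulated data for the comparison of day 3 with day 0 over 18193 genes. It recovered 72% of 50 genes changed by 0.5 on the log2 scale and 100% of 50 genes each changed by 1, 2 and 3. Of 17993 unchanged genes, 11 were called. Only 200 genes were changed, while 42.3% of genes were called in the data, so these rates need not hold there. Of 440 tests of unchanged lists, 3 were called. In these simulations each gene's noise was drawn independently, so they do not show how often lists of correlated genes are called falsely. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.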

Results

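Gene expression was measured on 4 arrays, with 2 samples of mouse embryonic stem cells at day 0 and 2 samples of epiblast-like tissue at day 3. In the culture method, dissociated stem cells re-aggregate quickly and float in medium without serum. Arrays of the same day were nearly alike, with Pearson's r across genes of 0.9975 at day 0 and 0.998 at day 3, against 0.9617 to 0.9619 between days. Genes are not independent replicates, so these correlations only describe the arrays. At least 2-fold differences separated 10 genes between the day 0 duplicates and 1 gene between the day 3 duplicates, against 1871 to 1923 genes between arrays of different days. The log2 signal at the 3' end minus that at the 5' end, a sign of RNA integrity, was 0.519 ± 0.229 at day 0 and 0.519 ± 0.032 at day 3 for the Gapdh control (mean ± SD, n = 2). For the Actb control it was 1.15 ± 0.17 and 1.22 ± 0.02.

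The comparison of day 3 with day 0 asked which genes differ between stem cells and epiblast-like tissue. The day 3 samples came from the aggregation culture, so effects of culture and medium cannot be told apart from a change of cell state. Among the genes, each represented by its probe set with the highest mean, the largest rise was that of Fgf5, a growth factor gene of the epiblast, from 3.62 ± 0.17 to 11.18 ± 0.14 on the log2 scale (mean ± SD, n = 2). A second Fgf5 probe set rose less, by 2.54, from 6.02 to 8.56, and was also called. Next after Fgf5 came Apob, encoding an apolipoprotein of lipid transport, with a log2 rise of 6.79 ± 0.12 (SE). Ctsh, a lysosomal protease gene, followed with 6.28 ± 0.10. The largest fall by the same choice of probe sets was that of Inhbb, encoding a subunit of activin B and inhibin B, from 10.69 ± 0.23 to 3.85 ± 0.28 (mean ± SD, n = 2), while its second probe set had a difference of -0.40 (adjusted p = 0.023 over all probe sets). Socs3, a feedback inhibitor of cytokine signalling, fell by 5.91 ± 0.08, and Stra8, a gene of meiotic entry, fell by 5.71 ± 0.09. All 6 had adjusted p-values of at most 2.8e-10 (limma, Benjamini-Hochberg).

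The other large rises were those of Irs4, a substrate of the insulin receptor (6.28), Clic6, of the chloride intracellular channel family (6.21), Cubn, an endocytic receptor (5.86), and Slc39a8, a zinc transporter (5.85). They were followed by Tox3 (5.03), the protease genes Ctsc (4.96) and Pga5 (4.90), the transcription factor gene Myb (4.77) and the calcitonin receptor gene Calcr (4.77). The other large falls were those of Calcoco2 (-5.07), Aard (-4.98), Pramel6 (-4.92), Prdm14 (-4.84), Khdc3 (-4.74), Gbx2 (-4.64), Ak7 (-4.63), Bcl3 (-4.61) and the adhesion molecule gene Icam1 (-4.61). Probe sets of 1 gene differed in size, and Irs4 had a second probe set with a log2 difference of 0.21 that was not called. From the mean of a gene's probe sets the rise was 3.94 for Apob, 3.25 for Irs4, 3.73 for Slc39a8 and 2.51 for Ctsc, and the difference was -3.62 for Inhbb and -2.96 for Pramel6. Without probe sets matching several transcripts it was 3.76 for Clic6 and -0.996 for Pramel6. Several of these genes were near or below the arrays' first quartile on one day, such as Fgf5, Irs4 and Apob at day 0 and Inhbb and Pramel6 at day 3, and no detection call separates such levels from background.

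Of 18193 genes, 7703 (42.3%) were called at an adjusted p under 0.05 (limma, Benjamini-Hochberg), with 3803 higher and 3900 lower at day 3. At least 2-fold differences were called for 1079 higher and 773 lower genes, and at least 4-fold for 310 and 196. The arrays of the 2 days did not overlap for any of the 7703 called genes, nor for 46.2% of the other genes, where chance gives 33.3% for 2 against 2. With an unmoderated test per gene, 1065 higher and 1084 lower genes were called, and testing each gene against a log2 difference of 1 called 664 higher and 472 lower. Brighter genes were called more often. Of the 9096 genes above the median level, tested alone, 2771 were called higher and 3226 lower. Counts of called members in lists and families of bright genes are to be read beside these shares.

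**Figure D1:**
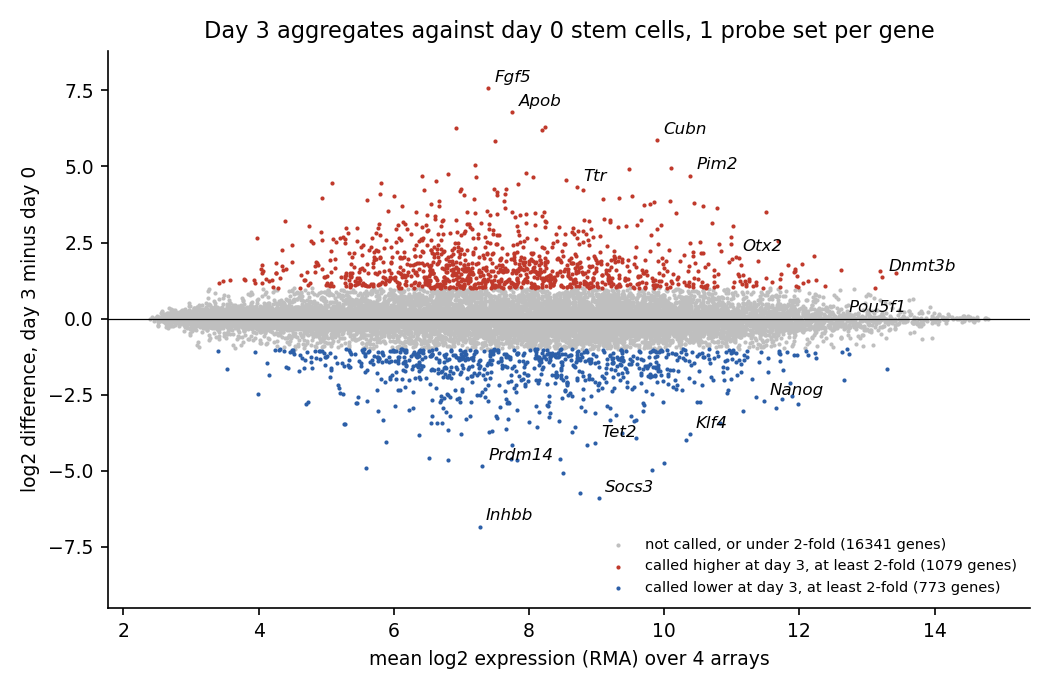
Each point is a gene, with its mean log2 expression over the 4 arrays on the horizontal axis and its log2 difference, day 3 minus day 0, on the vertical axis. The 1079 genes called at least 2-fold higher are red and the 773 called at least 2-fold lower are blue, from Fgf5 at 7.57 to Inhbb at -6.84, while Pou5f1 lies at 0.00.

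All 18 measured genes of naive pluripotency, the state of the pre-implantation embryo, fell. Prdm14, a transcriptional regulator of that state, fell by 4.84 ± 0.13 (SE) on the log2 scale, Gbx2, a homeobox gene, by 4.64 ± 0.12, and Klf4 by 3.80 ± 0.07. Nanog decreased from 12.83 ± 0.03 to 10.11 ± 0.22 and Zfp42, known as Rex1, from 13.16 ± 0.01 to 10.63 ± 0.07 (mean ± SD, n = 2). The count was 18 too when adjusted over the list alone. The list's median difference was -2.88 (camera adjusted p = 1.8e-18), with an adjusted p = 0.17 with an estimated correlation. The rise of visceral endoderm genes in the same arrays (list median 1.80) stands beside the change of this list and of every list that follows.

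Of 15 genes of general pluripotency, 11 fell, 2 rose and 2 were not called, and the counts adjusted over the list alone were the same. Pou5f1, which encodes Oct4, was at 12.64 ± 0.06 at day 0 and 12.64 ± 0.08 at day 3 (mean ± SD, n = 2), and its difference of 0.00 ± 0.06 (SE) was not called (limma, adjusted p = 0.98). Sox2 fell by 0.64 ± 0.07. The largest falls were those of Tdgf1, a Nodal co-receptor gene (-2.94), Gdf3 (-2.87) and Dppa2 (-2.64), while Foxd3 (1.66) and Lin28a (1.20) rose. The median was -0.49 (camera adjusted p = 1.8e-04), with an adjusted p = 0.34 with an estimated correlation.

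Of 20 genes of the formative and primed epiblast, 17 rose, 2 fell and 1 was not called. Adjusted over the list alone, 17 were higher and 3 lower. Beside Fgf5, the largest rises were those of Pim2, a kinase gene (4.70 ± 0.07, SE), and Cldn6, a tight junction gene (4.56 ± 0.12). Otx2, a homeobox gene of the epiblast and anterior embryo, rose from 10.05 ± 0.06 to 12.07 ± 0.10, and Dnmt3b, a de novo DNA methyltransferase gene, from 12.54 ± 0.16 to 13.91 ± 0.08 (mean ± SD, n = 2). Etv4 (-2.003) and Nodal (-1.61) fell. The median was 1.97 (camera adjusted p = 3.2e-10), with an adjusted p = 0.32 with an estimated correlation. Visceral endoderm genes rose in the same arrays, with a list median of 1.80.

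**Figure D2:**
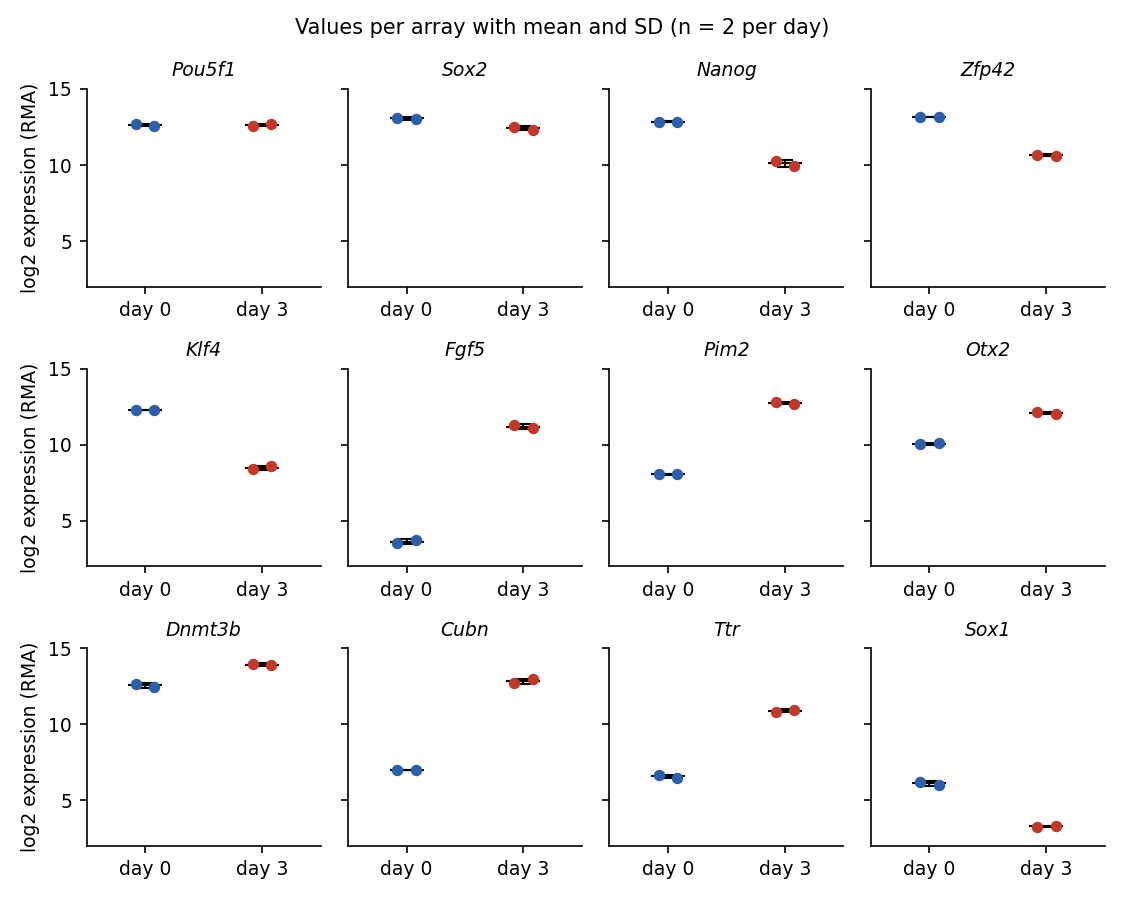
Log2 expression of 12 genes on each array, as points, with the mean and SD of each day in black (n = 2). Pou5f1 stays at 12.64 on both days, Sox2, Nanog, Zfp42 and Klf4 are lower at day 3, Fgf5, Pim2, Otx2, Dnmt3b, Cubn and Ttr are higher, and Sox1 falls from 6.10 to 3.28 by the probe set shown.

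Of 20 genes of primitive and visceral endoderm, an extra-embryonic tissue, 19 rose and 1, Gata6, was not called, over all genes and adjusted over the list alone alike. Apob and Cubn were among the 12 largest rises by the probe sets kept, 1 per gene. Ttr, encoding a thyroid hormone transport protein, rose from 6.55 ± 0.11 to 10.88 ± 0.09 (mean ± SD, n = 2) by its probe set with the highest mean. Its other 3 probe sets rose by 8.63, 8.78 and 8.97 on the log2 scale, more than the probe set kept for Fgf5, from levels below the arrays' first quartile. Gata6, a transcription factor gene of primitive endoderm, was at 9.71 ± 0.21 and 9.46 ± 0.20, with a difference of -0.25 ± 0.11 (SE, limma adjusted p = 0.11). Without day 0 replicate 2 that difference was -0.40 and was called (adjusted p = 0.0029, against up to 0.62 without another array). It was -0.39 without day 3 replicate 2, -0.099 without day 0 replicate 1 and -0.11 without day 3 replicate 1, and was not called. The median of the list was 1.80 (camera adjusted p = 2.3e-13), with an adjusted p = 0.32 with an estimated correlation.

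Of 18 early neural plate genes, 8 rose, 3 fell and 7 were not called, and adjusted over the list alone 9 were higher and 3 lower. Sox3 (4.25 ± 0.10, SE) and Sox11 (3.94 ± 0.13), transcription factor genes of neural progenitors, rose most. Sox1, an early marker of neural fate, fell by 2.82 ± 0.13, and Sox21 by 1.32 ± 0.11. Sox1 and Sox3 each had a second probe set that was not called, with differences of 0.09 and 0.35. That of Sox1 lay near the arrays' first quartile on both days (4.27 and 4.37). The list's median was 0.36 and camera did not call it (adjusted p = 0.062). It was called for genes above the median level (median 1.22, adjusted p = 0.022), from the mean of a gene's probe sets (0.40, adjusted p = 0.032), and without day 0 replicate 1 or day 3 replicate 1 (adjusted p = 0.026 and 0.041, against up to 0.093 without another array). Without day 3 replicate 2 the median was 0.22.

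Of 14 genes of the primitive streak and mesendoderm, 5 rose, 0 fell and 9 were not called, and the counts adjusted over the list alone were the same. Lhx1 rose by 3.86 ± 0.18 (SE), Eomes by 2.46 ± 0.10, Foxa2 by 2.45 ± 0.09 and Gata4 by 1.03 ± 0.11, the last with 1 of its 2 probe sets called. These 4 transcription factor genes are also expressed in visceral endoderm, whose list had a median of 1.80. The streak list's median was 0.15 (camera adjusted p = 0.038), with an adjusted p = 0.32 with an estimated correlation. Among 10000 random lists matched on level it lay at the 93.6th percentile. The list was not called after renewed quantile normalization (adjusted p = 0.051) or on ranks (adjusted p = 0.077).

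Of 13 trophectoderm genes, 5 rose, 2 fell and 6 were not called, and adjusted over the list alone 5 were higher and 4 lower. Krt18 (2.95 ± 0.12, SE) and Krt8 (2.07 ± 0.12), keratin genes of simple epithelia, Plac1 (2.49 ± 0.16) and Eomes rose, and Cdx2, a trophectoderm transcription factor gene, fell by 0.61 ± 0.13. Camera did not call the list (median 0.15, adjusted p = 0.17). Its median turned to -0.06 with the mean of a gene's probe sets and to -0.08 without probe sets matching several transcripts, while it was 2.26 and called for the 4 members above the median level (adjusted p = 0.022) and 0.10 and called without day 0 replicate 1 (adjusted p = 0.025, against up to 0.25 without another array). Without day 0 replicate 2 or day 3 replicate 1 it was 0.039 and 0.085. Eomes and the keratin genes rose in the same arrays as visceral endoderm genes, whose list had a median of 1.80.

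Of 15 fibroblast genes, which would mark feeder cells, 4 rose, 2 fell and 9 were not called, over all genes and adjusted over the list alone alike. The surface antigen gene Thy1 rose by 1.82 ± 0.10 (SE) and the proteoglycan gene Dcn by 0.96 ± 0.13, while the smooth muscle gene Tagln fell by 1.31 ± 0.11. Acta2, another smooth muscle gene, fell by 1.18 ± 0.11 with 1 of its 3 probe sets called. Without probe sets matching several transcripts its difference was 0.21 and was not called. That value came from a probe set below the arrays' first quartile on both days (3.67 and 3.88), where a fall could not be seen. The median was 0.15 (camera adjusted p = 0.37), and 0.23 without day 3 replicate 2.

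Of 5 measured genes of cells resembling the 2-cell embryo, 4 fell, 0 rose and 1 was not called, and adjusted over the list alone all 5 were lower. Usp17la fell by 2.52 ± 0.13 (SE) and Arg2, an arginase gene, by 1.23 ± 0.11. Tcstv1 fell by 0.83 ± 0.26, but lost its call without the intensity trend (adjusted p = 0.076) and without day 0 replicate 2 (adjusted p = 0.14) or either day 3 array (adjusted p = 0.14 and 0.21), at -0.32, -0.91 and -0.76. Without day 0 replicate 1 it was -1.35 and called. The median was -0.83 (camera adjusted p = 0.0079), with an adjusted p = 0.32 with an estimated correlation. This median is the value of Tcstv1, and the list's median ranged from -1.19 to -0.65 with 1 array left out.

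Germline genes mostly fell, with 12 of 16 lower, 1 higher and 3 not called, and the counts adjusted over the list alone were the same. Hormad1 (-3.29 ± 0.13, SE), a gene of meiotic chromosome axes, Stk31 (-3.24 ± 0.11) and Dazl (-2.65 ± 0.12), encoding a germ cell RNA-binding protein, fell most. Sycp3, a component of the synaptonemal complex, rose by 2.45 ± 0.07. The median was -1.11 (camera adjusted p = 2.9e-05), with an adjusted p = 0.32 with an estimated correlation. It was -1.88 for genes above the median level.

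Targets and components of the signalling pathway of leukemia inhibitory factor (LIF) and Stat3 fell, with 13 of 15 lower, 0 higher and 2 not called, and 13 lower adjusted over the list alone. Beside Socs3, Gbx2 and Klf4, the transcriptional co-regulator gene Bcl3 fell by 4.61 ± 0.11 (SE). Klf4, Klf5, Gbx2, Tfcp2l1 and Nr0b1 also stood in the naive pluripotency list, so the lists are not independent. The median was -2.25 (camera adjusted p = 8.8e-13), with an adjusted p = 0.17 with an estimated correlation. It was -1.37 from the mean of a gene's probe sets.

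Genes of Nodal and BMP signalling went both ways, with 7 of 16 higher, 8 lower and 1 not called, over all genes and adjusted over the list alone alike. Tdgf1 (-2.94 ± 0.08, SE), the inhibitory Smad gene Smad6 (-2.90 ± 0.12) and the ligand genes Bmp4 (-2.25 ± 0.08) and Nodal (-1.61 ± 0.12) fell. By at least 2-fold, 8 genes of the list fell and 3 rose, the largest rise being 1.91. The median was -0.67 (camera adjusted p = 0.37), and -1.30 for genes above the median level. Of 16 genes of FGF and ERK signalling, 7 rose, 6 fell and 3 were not called, and adjusted over the list alone 8 were higher and 6 lower. The ligand genes Fgf5 and Fgf15 (2.80 ± 0.21) rose, and Etv4, a transcription factor gene induced by this pathway, fell by 2.003 ± 0.10. The median was 0.09 (camera adjusted p = 0.89) and turned to -0.0040 for genes above the median level. It was 0.15 without day 0 replicate 1, 0.029 from the mean of a gene's probe sets and 0.048 without probe sets matching several transcripts.

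Of 12 Wnt targets, 4 rose, 3 fell and 5 were not called, over all genes and adjusted over the list alone alike. Lef1 (2.83 ± 0.14, SE), Dkk1 (1.67 ± 0.10), Ccnd1 (0.70 ± 0.07) and Rnf43 (0.65 ± 0.13) rose, and Notum, a secreted inhibitor, fell by 1.39 ± 0.11. The list's median was -0.06, while its mean of 0.27 and the direction of both camera and fry were upward (camera adjusted p = 0.72). For genes above the median level the median was 0.11. It was -0.038 without day 0 replicate 1, -0.12 without day 0 replicate 2 and -0.028 without day 3 replicate 1.

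Genes of epithelial adhesion and polarity rose, with 14 of 20 higher, 2 lower and 4 not called, over all genes and adjusted over the list alone alike. The claudin genes Cldn6 (4.56 ± 0.12, SE) and Cldn7 (4.02 ± 0.07) and Podxl, encoding a sialomucin of apical membranes (3.23 ± 0.07), rose most, while the polarity kinase gene Prkci (-0.83 ± 0.05) and the integrin gene Itga6 (-0.34 ± 0.06) fell. The median was 1.14 (camera adjusted p = 2.8e-07), with an adjusted p = 0.32 with an estimated correlation. Visceral endoderm genes rose in the same arrays, with a list median of 1.80.

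Of 11 genes of the DNA methylation machinery, 8 fell, 2 rose and 1 was not called, and the counts adjusted over the list alone were the same. Tet2, which encodes an enzyme that oxidizes methylcytosine, fell from 11.03 ± 0.11 to 6.93 ± 0.19 (mean ± SD, n = 2). Zfp57, a protector of imprints, fell by 1.94 ± 0.13 (SE) and Dnmt3l, a cofactor of de novo methylation, by 1.51 ± 0.06, while the methyltransferase genes Dnmt3b (1.37 ± 0.07) and Dnmt3a (0.41 ± 0.06) rose. The median was -0.45 (camera adjusted p = 0.0022), with an adjusted p = 0.32 with an estimated correlation.

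All 14 measured genes of cholesterol synthesis rose, also adjusted over the list alone. The largest rises were those of Sc5d (1.42 ± 0.09, SE), Cyp51 (1.20 ± 0.07) and Lss (0.95 ± 0.08), which encode enzymes of the sterol branch. The median was 0.70 (camera adjusted p = 4.5e-08), with an adjusted p = 0.32 with an estimated correlation. Visceral endoderm genes rose in the same arrays as this list and the next, with a list median of 1.80. Of 16 glycolysis genes, 10 rose, 4 fell and 2 were not called, and adjusted over the list alone 10 were higher and 5 lower. The lactate transporter gene Slc16a3 (2.18 ± 0.16), Tpi1 (1.53 ± 0.10) and Aldoc (1.40 ± 0.15) rose, while Pfkp (-1.24 ± 0.12) and the hexokinase genes Hk2 (-0.85 ± 0.07) and Hk1 (-0.56 ± 0.08) fell. The median was 0.79 (camera adjusted p = 0.028), with an adjusted p = 0.68 with an estimated correlation. That call was also lost without the intensity trend (adjusted p = 0.053), for genes above the median level (0.083), without day 3 replicate 1 (0.058, median 0.67, against down to 0.0045 without another array), with fry (0.074) and on ranks (0.076).

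Of 18 genes of oxidative phosphorylation, 7 fell, 1 rose and 10 were not called, over all genes and adjusted over the list alone alike. Ndufs1 (-0.47 ± 0.06, SE) and Cox4i1 (-0.38 ± 0.05), encoding respiratory chain subunits, fell, and Ndufs4 rose by 0.41 ± 0.06 with 1 of its 4 probe sets called, a call lost with the mean of its probe sets (0.10). The median was -0.04 (camera adjusted p = 0.17). Among 10000 random lists matched on level it lay at the 49.8th percentile. It was 0.01 without day 3 replicate 1, and -0.07 and called without day 3 replicate 2 (adjusted p = 0.045, against up to 0.54 without another array). It was -0.017 after renewed quantile normalization and -0.069 from the mean of a gene's probe sets. Of 19 mitotic genes, 11 fell, 1 rose and 7 were not called, and adjusted over the list alone 1 was higher and 13 lower. The changes were small, the largest being those of the kinesin gene Kif20a (-0.60 ± 0.08), the checkpoint kinase gene Bub1b (-0.56 ± 0.08) and Aurka (-0.53 ± 0.07). The median was -0.25 (camera adjusted p = 0.0022), with an adjusted p = 0.32 with an estimated correlation.

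Of 15 genes of the p53 and stress response, 5 rose, 4 fell and 6 were not called, over all genes and adjusted over the list alone alike. Ddit4, an inhibitor of mTOR signalling, rose by 1.37 ± 0.12 (SE), Atf3 by 0.83 ± 0.12 and the proapoptotic gene Bbc3 by 0.62 ± 0.11, while Gadd45a fell by 1.73 ± 0.07, Perp by 0.90 ± 0.13, Mdm2 by 0.75 ± 0.08 and Asns by 0.44 ± 0.08. Without probe sets matching several transcripts Asns had a difference of -0.27 and was still called. The median of 0.07 differed in sign from the mean of -0.01 and from the downward direction of camera (adjusted p = 0.92). The median was -0.04 without day 3 replicate 2, 0.19 without day 3 replicate 1, 0.17 without day 0 replicate 1 and 0.014 without day 0 replicate 2. It was 0.13 after renewed quantile normalization, 0.030 for genes above the median level and 0.0067 from the mean of a gene's probe sets.

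Of 16 imprinted genes, 10 rose, 5 fell and 1 was not called, over all genes and adjusted over the list alone alike. Ndn (1.996 ± 0.10, SE), Peg3 (1.85 ± 0.09) and Nnat (1.75 ± 0.11) rose most, and Slc38a4 (-1.73 ± 0.09), Peg10 (-1.36 ± 0.12) and Phlda2 (-1.16 ± 0.10) were among the 5 that fell. The median was 0.39 and camera did not call the list (adjusted p = 0.12), except without day 0 replicate 1 (0.39, adjusted p = 0.046, against up to 0.14 without another array). It was 0.23 from the mean of a gene's probe sets.

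**Figure D3:**
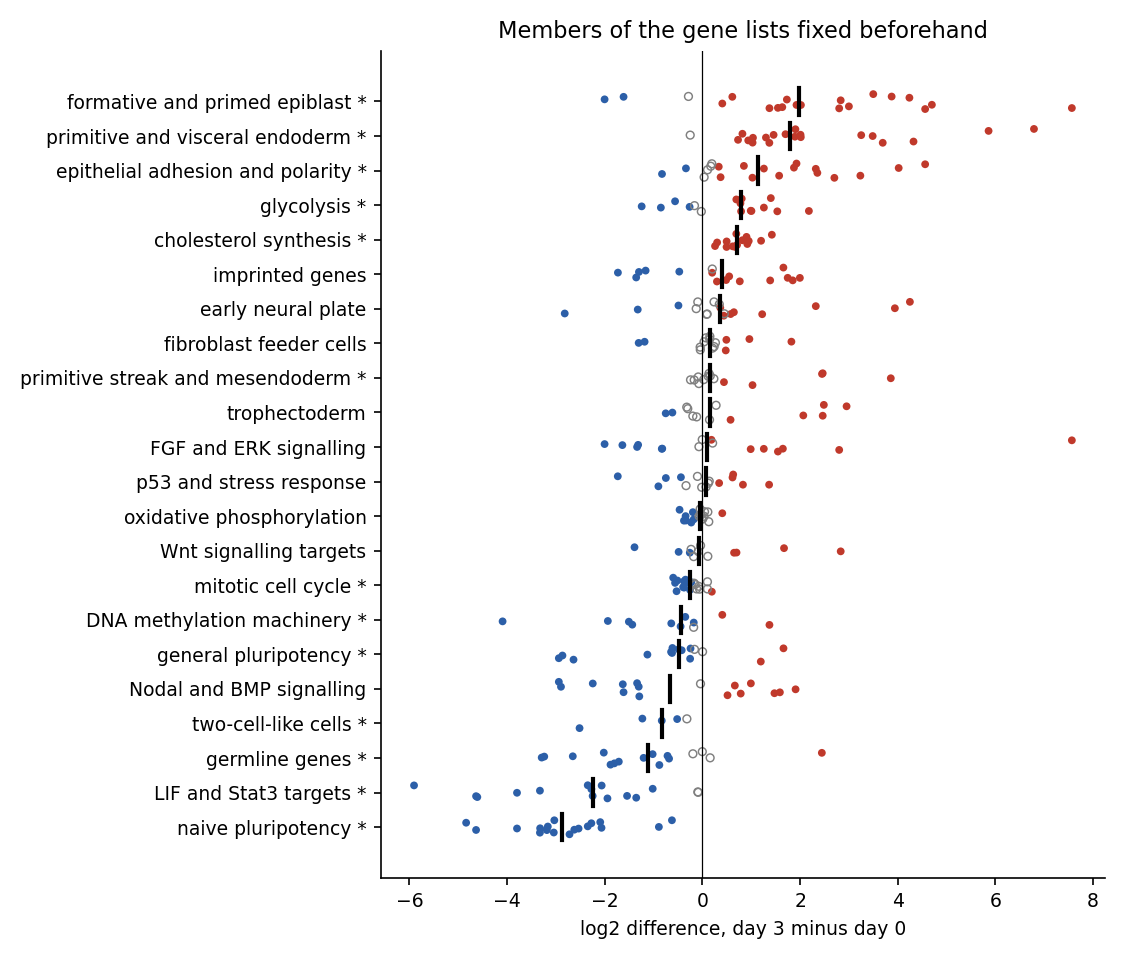
Log2 difference, day 3 minus day 0, of each measured member of the 22 lists, with called members filled (red higher, blue lower), other members open and the median as a black bar. An asterisk marks the 13 lists called by camera at its preset correlation, from naive pluripotency at a median of -2.88 to the formative and primed epiblast at 1.97.

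Across the 22 lists, camera called 13 at its preset correlation and fry called 17. With an estimated correlation camera called 0, while 2 lists, naive pluripotency and the LIF and Stat3 targets, had an unadjusted p under 0.05. These 2 lists share members. From the mean of a gene's probe sets, 21 of the 110 named genes differed by over 1.5 times from the value by 1 probe set. Besides the 6 given with the largest differences, these were Ttr (7.68), Sox3 (2.30), Sox1 (-1.36), Ndn (1.17), Peg3 (1.04), Sc5d (0.89), Aldoc (0.81), Dnmt3a (0.80), Dcn (0.52), Gata4 (0.51), Mdm2 (-0.46) and Cdx2 (-0.37), all still called, and Acta2 (-0.22), Ndufs4 (0.10) and Xist (-0.22), which were not called.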

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

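All alternatives here were chosen in advance. Of 58 counts of genes under the alternatives, 49 stayed within 1.5 times the reported count. An unmoderated test per gene called 1065 higher and 1084 lower genes, and 589 and 465 at 2-fold or more, since 2 residual degrees of freedom give it little power. Genes above the median level gave 677 at least 2-fold higher genes among the 9096 tested, and a test against a log2 difference of 1 gave 664 higher and 472 lower. Testing all 45037 probe sets called 6409 higher and 7522 lower, more because more were tested. With 1 array left out, the lone array of a day being assumed to vary like the other day's, 2908 to 3692 genes were higher and 2895 to 3748 lower, and 1075 to 1111 and 775 to 795 by at least 2-fold. The replicate block gave 3789 higher and 3871 lower genes, 1079 and 773 by at least 2-fold, and changed no list's call. The deviations of same-numbered arrays correlated at -0.0167 across genes, and with 2 pairs the arrays share only a number.

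Of 327 list results, 288 kept their direction and their side of the threshold. Camera with an estimated correlation kept no call among the 13 lists, at unchanged medians. Its adjusted p was 0.17 for naive pluripotency (-2.88) and LIF and Stat3 targets (-2.25), 0.34 for general pluripotency (-0.49) and 0.68 for glycolysis (0.79). It was 0.32 for the formative and primed epiblast (1.97), endoderm (1.80), streak (0.15), 2-cell-like cells (-0.83), germline (-1.11), epithelial (1.14), DNA methylation (-0.45), cholesterol (0.70) and mitotic (-0.25) lists. This variant rests on 2 residual degrees of freedom and so has little power. The streak, LIF and Stat3, and mitotic lists lost their calls at estimated correlations of -0.069, -0.0575 and -0.011, below the preset 0.01. The losses therefore do not show that correlation between genes accounts for the calls. For the rest of this paragraph the cause was not tested. Glycolysis also lost its call without the intensity trend (0.79), above the median level (0.78), with fry and on ranks, and ranged from 0.67 to 0.90 with 1 array left out. The streak list lost it after renewed quantile normalization (0.14) and on ranks (0.15). The neural list gained a call above the median level (1.22), from the mean of probe sets (0.40) and with fry (0.36), and ranged from 0.22 to 0.41. The trophectoderm list gained one above the median level (2.26) and with fry (0.15), turned to -0.056 from the mean of probe sets and to -0.082 without probe sets matching several transcripts, and ranged from 0.039 to 0.21. Fry also called the fibroblast (0.15), Wnt (-0.062) and imprinted (0.39) lists. Above the median level the FGF median turned to -0.0040 and the Wnt median to 0.11. With 1 array left out, medians ranged from 0.34 to 0.42 for imprinted genes, from -0.074 to 0.0067 for oxidative phosphorylation and from -0.044 to 0.19 for the stress response.

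Of 1408 results of the 110 named genes, 1348 kept both, and 47 genes lost their call in the unmoderated test. Outside it 6 genes changed. Pou5f1 turned to -0.0063 with median centring and ranged from -0.057 to 0.062 with 1 array left out. Without probe sets matching several transcripts, Acta2 turned to 0.21 and Xist to 0.083. The probe sets used there lay below the arrays' first quartile on both days, so they do not show a change of direction. The others were Tcstv1, Ndufs4 and Gata6. The cause was not tested. The files used here give no background or detection call, so what signal over background limits was not analysed here.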

Other observations

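The tests of gene families, of the X chromosome by quartile, of fibroblast genes against endoderm genes, of probe sets for the endoderm list, and both tests of the spiked transcripts were chosen only after the result was seen. The gene symbols were grouped by shared stem, and 295 families of at least 8 genes were tested with camera, which called 4 higher and 11 lower at its preset correlation and 0 with an estimated correlation. Of 21 cadherin genes (Cdh), 11 rose and 0 fell, with a median log2 difference of 0.39 (adjusted p = 0.0087, and adjusted p = 0.95 with an estimated correlation). Cdh10 rose by 3.89 ± 0.13 (SE) and Cdh2, which encodes N-cadherin, by 2.32 ± 0.12. Cdh1, which encodes E-cadherin and had the highest level of the family, rose by 1.26 ± 0.07, from 11.61 to 12.87. Among the 11, Cdh7 and Cdh8 lay below the arrays' first quartile on both days. Of 19 tetraspanin genes (Tspan), 11 rose and 4 fell, with a median of 0.51 (adjusted p = 0.033, and adjusted p = 0.95 with an estimated correlation), and Tspan12 rose by 3.53 ± 0.12. Of 12 genes with the stem Lrp, most of them of LDL receptor-related proteins, 8 rose and 1 fell, with a median of 0.51 (adjusted p = 0.033, and adjusted p = 0.95 with an estimated correlation). Of 10 Rassf genes, 7 rose and 1 fell, with a median of 0.57 (adjusted p = 0.039, and adjusted p = 0.95 with an estimated correlation). Visceral endoderm genes rose in the same arrays as these 4 families, with a list median of 1.80, and Lrp2, the Lrp gene with the largest rise (1.90), is itself a member of that list.

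Of the 11 families called lower at the preset correlation, each had an adjusted p = 0.95 with an estimated correlation, and visceral endoderm genes rose in the same arrays (list median 1.80). Of 10 genes with the stem Mcm, 8 fell and 0 rose, with a median of -0.28 (adjusted p = 0.020). Only some of these genes encode subunits of the replicative helicase. The largest falls were those of Mcm3ap (-0.84) and Mcm10 (-0.58), which do not, and Mcm3 and Mcm7 were not called. Of 25 RNA polymerase genes (Polr), 16 fell and 1 rose, with a median of -0.30 (adjusted p = 0.0087), and Polr2e fell by 1.27 ± 0.10 (SE). With an estimated correlation both families had an adjusted p = 0.95. Of 47 and 29 genes of mitochondrial ribosomal proteins (Mrpl and Mrps), 24 and 16 fell and 4 and 3 rose, with medians of -0.22 and -0.25 (adjusted p = 0.0087 each, and adjusted p = 0.95 with an estimated correlation). Of 23 Taf genes, 13 fell and 2 rose, with a median of -0.57 (adjusted p = 0.019, and adjusted p = 0.95 with an estimated correlation). Of 11 Pramel genes, 4 fell and 0 rose, with a median of -0.23 (adjusted p = 0.033, and adjusted p = 0.95 with an estimated correlation), and Pramel7 fell by 3.42 ± 0.13. The other 5 were the helicase families Ddx (20 of 35 lower, median -0.21, adjusted p = 0.0087) and Dhx (9 of 16 lower and 1 higher, -0.30, 0.033), the autophagy genes Atg (11 of 18 lower, -0.34, 0.022), the Wdr genes (29 of 60 lower and 6 higher, -0.22, 0.0098) and the nucleoporin genes Nup (11 of 19 lower, -0.18, 0.039), all with an adjusted p = 0.95 with an estimated correlation. Among 10000 random lists matched on level, the Nup median lay at the 11.02nd percentile and the other 10 at the 2.23rd or lower. These families were picked by camera for low values on the same arrays, so low percentiles follow from the choice and add no support.

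Endoderm markers were higher at day 3, with a list median of 1.80. The choice of probe sets as the cause is argued against, since the lower of the medians under 2 other choices was 1.49. A lower share of the main cell type stays open, since the fibroblast genes, which the endoderm median exceeded by 1.65, lay near the floor (median level 4.78, against 5.79 over all probe sets), the neural and trophectoderm genes went both ways, and the 5 genes of cells resembling the 2-cell embryo, which mostly fell, are few. A second list of 18 visceral endoderm genes, fixed before their values were seen, had a median of 0.74, with 10 higher and 1 lower (camera adjusted p = 8.7e-05, and adjusted p = 0.12 with an estimated correlation), and 12 genes of parietal endoderm had a median of 0.88, with 7 higher and 4 lower (camera adjusted p = 0.074). Cells with a visceral endoderm program in the day 3 aggregates are a candidate source, and expression of these genes in the epiblast-like cells stays open, since a mixture was not resolved.

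Genes of the X chromosome were higher at day 3 than those of the autosomes, with medians of 0.09 over 618 genes and 0.01 over 17516, and with 31.9% called higher and 18.1% lower against 20.6% and 21.6%. Camera did not call the X chromosome among 20 chromosomes (adjusted p = 0.22, and adjusted p = 0.76 with an estimated correlation). A difference in level is argued against, since the X median lay at the 100th percentile of 10000 autosomal lists matched on level, whose highest median was 0.05. One uniform shift of the chromosome as the whole difference is argued against as well. Among genes at a level of 8 or more, the third quartile was shifted by 0.45 more than the first (95% bootstrap interval 0.25 to 0.57). The first quartile was itself 0.09 above that of the autosomes (interval 0.02 to 0.20). A smaller shift shared by the X genes, beside a wider spread, therefore stays open. Both the matched lists and the bootstrap drew genes as if independent, so they give more certainty than genes that move together allow. Xist had a difference of -0.78 ± 0.10 (SE) by 1 of its 3 probe sets. Without probe sets matching several transcripts the difference was 0.08, by a probe set below the arrays' first quartile on both days (3.605 and 3.689). The number of active X chromosomes was not tested and may differ between days.

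On the array of day 3 replicate 2, all 24 probe sets of spiked bacterial transcripts were lower than on replicate 1, with a median log2 difference of -1.79. The day 0 duplicates differed by -0.40. Weaker hybridization as the whole cause is argued against by the 18 probe sets of hybridization controls. They were also all lower on that array, but by a median of -0.11, and passed through the same normalization. Both kinds of control had several probe sets per transcript, so the probe sets are not separate pieces of evidence. An effect of the array on all genes stays open, since RMA makes arrays alike before the 0.0055% of genes at least 2-fold apart between the duplicates was counted. A different amount of spike per sample was not tested, and no biological explanation was tested.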
